A study of Danio rerio with 15 samples.

How the data were processed

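Messenger RNA of whole wild-type AB zebrafish was sequenced at 100 hours post fertilization (hpf), per the labels' protocols. Embryos were exposed through the water from 96 to 100 hpf, for 4 hours, to 0.01% v/v dimethyl sulfoxide (DMSO, the solvent control), to 50 nM tris(4-chlorophenyl)methane (TCPM) or to 50 nM tris(4-chlorophenyl)methanol (TCPMOH). Each library came from a pool of 8 to 10 embryos, and each of the 3 groups has 5 libraries, 15 in all, made with a stranded mRNA kit. The series design mentions 3 experimental replicates but does not say which pool belongs to which. With 5 pools per group, some pools of a group would then come from the same experiment. Pools of one experiment may share a clutch and a day, and the p-values measure the spread between these pools only.

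FastQC, cutadapt, STAR, featureCounts and DESeq2 are named in the submitters' processing notes, without versions. Gene models came from a GTF of version 4.3.2 with Ensembl release 99 identifiers, per the file headers. The genome build is not given in the sources used here, so coordinates are printed as deposited, and whether they count from 0 or 1 is not stated. The table used here is the authors' own DESeq2 result for DMSO and TCPMOH libraries, with 36351 genes. It has 0 columns named for a sample or group, so no value per library was used. The deposited base mean is a signal that is never negative, the mean of DESeq2-normalized counts over the fitted libraries. The deposited fold change is a log2 value, and the deposited standard error (SE) is on the same log2 scale. The Wald statistic is a score that the authors deposited, and it equals the log2 fold change divided by its SE. Each p-value that the authors deposited is the two-sided Wald p-value, and each adjusted p-value carries the Benjamini-Hochberg adjustment. Recomputing that adjustment over the 19257 genes that have one gave values within 5.17e-06 of the deposited ones.

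The file header does not say which group is the numerator of the fold change. The deposited comparison is named with DMSO before TCPMOH, an order that could mean DMSO as the numerator. A negative value is nonetheless read here as lower with TCPMOH than with DMSO, with the control as reference. All directions, "higher" and "lower" alike, rest on that reading and would swap together under the other one. The deposited log2 fold changes appear to be shrunken toward 0. The median SE was 0.0245 at base means from 0 to 1, 0.123 from 20 to 50 and 0.0704 from 1000 to 3000, and no SE exceeded 0.124. Such a rise and fall arises with a normal prior on the fold change, and the largest SE corresponds to a prior standard deviation of 0.248. No source used here states whether a prior was used. If one was, the printed folds understate the change, and the Wald statistics are those of the authors' test either way.

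Of the 36351 genes, 4014 had a base mean of 0, 32336 had a p-value and 19257 had an adjusted p-value, all of the latter with a base mean of at least 49.1. A gene was called changed at an adjusted p under 0.05 in the authors' DESeq2 Wald test, as planned for a table of the authors' statistics alone. Count models, a replicate block, leaving out replicates, library checks and regroupings of the samples need values per library and were not run. TCPM libraries were not analysed here. The median SE of the tested genes was 0.0907 and their median base mean was 416. Depth per library is unknown here, and the base means sum to 24808364 normalized counts.

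Before the data were examined, 41 gene lists were written, covering xenobiotic, endocrine, metabolic, stress and clock responses and markers of the cell types of a whole larva. The 40 lists with at least 5 tested members were tested with cameraPR (limma 3.58.1, R 4.3.3) on the Wald statistics, with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. An estimated correlation needs values per library, so a preset correlation of 0.05 and a rank version were run in its place. Intervals of list medians are 95% bootstrap intervals over genes (10000 draws), and genes are not independent replicates. Where a symbol had several entries, the one with the highest base mean stood for it in the lists. Ensembl identifiers were given for 29086 entries, of which 26047 matched the gene name table. Symbols are those of the authors' deposited table. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

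The genes named were set by a rule fixed beforehand. It takes the 12 called genes with the highest and the 12 with the lowest log2 fold change, with a base mean of at least 20 and a symbol that is not an accession, clone or project name. From each list it takes at most 4 called members by smallest p, and it always takes cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra, cyp3a65, hmox1a, gstp1, pck1, ins, vtg1, fkbp5, per1a and nr1d1. A gene named outside the rule is said to be chosen after its value was seen. Some genes that the rule or the lists include are not reported here.

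Also fixed beforehand were other settings, namely adjusted p thresholds of 0.1 and 0.01, no filter on low means, a base mean of at least 50, and a minimum absolute log2 fold change of 1. Chosen after seeing the data were a shift of all fold changes that makes the groups' summed values equal, an empirical null that divides the Wald statistics by their spread, removal of the trend with gene span (a running median over 1001 genes), both of the last 2 together, the inferred shrinkage undone, and the list tests with other correlations and ranks. The summed values per group were worked out from the base means and the deposited folds, not from counts. If those folds are shrunken, the shift may understate the difference in sums. The adjustment and the calls were tested on simulated data for the comparison of TCPMOH and DMSO, with 19257 genes at their own SEs and 200 of them changed. Of the changed genes, 30.0% were recovered at a log2 change of 0.25, 96.0% at 0.5, and 100.0% at 0.75 and at 1, and 7 unchanged genes were called. The simulation covers the adjustment step and takes the SEs as given. If the deposited folds and SEs are shrunken, the simulated changes are on that shrunken scale. Unshrunken changes of the same sizes would then be recovered less often. Of the 2 lists shifted in the simulation, by 1.5 Wald units, both were called, and 0 of the others. The simulated statistics were independent draws from a standard normal distribution. In the data the Wald statistics had a wider spread of 1.30, and genes of a list may be correlated. The simulated counts of false calls therefore do not measure the error rate in these data.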

Results

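The series asked how a short exposure to TCPM or TCPMOH late in zebrafish embryonic development changes the transcriptome. Both are chlorinated contaminants, and they differ at the central carbon, which carries a hydroxyl group in TCPMOH. The data comprise 5 DMSO, 5 TCPM and 5 TCPMOH pools of whole animals at 100 hpf, after 4 hours at 50 nM of either compound. The comparison of TCPMOH with DMSO is described here from the authors' deposited table. TCPM against DMSO and TCPMOH against TCPM were not analysed here, so the compounds are not compared. Directions read a negative fold change as lower with TCPMOH, an assumption that takes the control as reference. The header does not name the numerator, and the deposited comparison is named with DMSO first. All directions below could therefore be reversed.

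With negative values read as lower, the lists of heat shock genes and of aryl hydrocarbon receptor targets were lower after TCPMOH exposure. Clock genes changed in both directions, and the cone opsin genes opn1mw2 and opn1sw2 were higher. Among 19257 genes with an adjusted p, 516 were called changed in the authors' deposited table (DESeq2 Wald test, Benjamini-Hochberg adjusted p under 0.05), 146 higher and 370 lower. Changes were small, with a median absolute log2 fold change of 0.32 among the higher genes and 0.34 among the lower ones, and 54 genes reached 0.5. The share of lower genes was 71.7%. It fell to 38.0%, with 355 genes higher and 218 lower, when all fold changes were shifted by 0.048 log2 units, an alternative chosen after seeing the data. The shift makes the groups' summed values equal, as worked out from the base means and the deposited folds. Those folds appear shrunken, so the shift may understate the difference in sums. The balance of higher and lower calls thus depends on the centring. Under the other reading of the fold change, the 71.7% and the 38.0% would be shares of higher genes. With the Wald statistics divided by their own spread (the empirical null, also chosen after seeing the data), 121 genes were called.

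**Figure D1:**
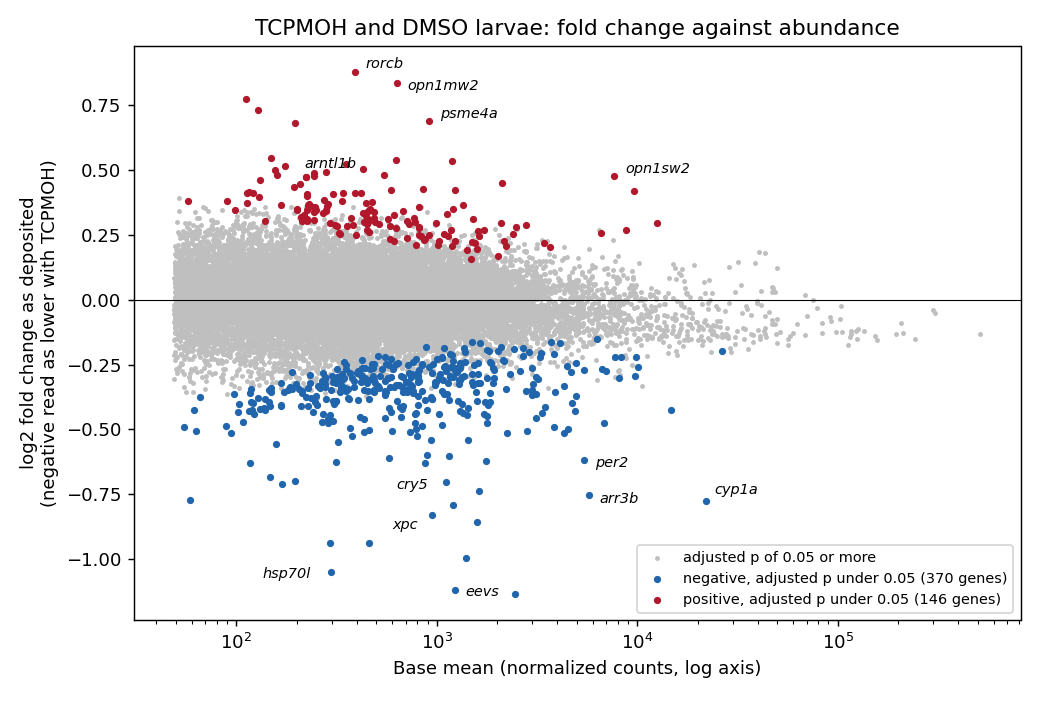
Deposited log2 fold change (vertical axis, negative read as lower with TCPMOH) against base mean in normalized counts (horizontal log axis), one point per gene with an adjusted p. Blue points are the 370 genes called lower and red points the 146 called higher (authors' DESeq2 Wald test, adjusted p under 0.05), and grey points did not pass. The called genes run from -1.14 to 0.88.

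The lowest named gene was eevs, which encodes a synthase of the gadusol pathway, a sunscreen compound of fish. In the authors' deposited table its log2 fold change was -1.12 (SE 0.108; DESeq2 adjusted p = 1.81e-21), 2.18-fold lower at a base mean of 1231, and the gene lies on chromosome 6 from 43438074 to 43449013. Among the other most reduced genes in the authors' deposited table were xpc, a DNA damage recognition factor, at -0.83 (SE 0.0814), gch2, a GTP cyclohydrolase of pigment cells, at -0.79 (SE 0.107), and the phosphate hormone gene fgf23 at -0.77 (SE 0.123). The heme-binding protein gene hebp2, at -0.74, and the transporter gene abcg2b, at -0.70, were also lower in the authors' deposited table. Only 3 called genes had an absolute log2 fold change of at least 1 in the authors' deposited table, namely eevs, hsp70l and si:ch211-132b12.7, the last chosen after its value was seen (-1.14). All 3 were lower. The deposited folds appear shrunken toward 0, and with the inferred shrinkage undone, an alternative chosen after seeing the data, 15 called genes reached 1, 4 higher and 11 lower. In that version eevs stood at -1.51, fgf23 at -1.35 and gch2 at -1.05. The SE of fgf23 is close to the largest of 0.124, where the inferred correction is largest.

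Of the 12 most raised named genes, rorcb led at 0.88 (SE 0.111; DESeq2 adjusted p = 2.52e-12), 1.84-fold higher in the authors' deposited table. It encodes a ROR family nuclear receptor and lies on chromosome 2 from 49410023 to 49454501. The proteasome activator gene psme4a stood at 0.69 (SE 0.113) in the authors' deposited table. Others among the 12 in the authors' deposited table were the sorting nexin gene snx19a (0.55), the cell cycle inhibitor cdkn1d (0.54), ndrg1b (0.52), alpk2 (0.50), the Fanconi anemia gene fanci (0.50) and ccdc141 (0.49). Of these, ndrg1b lost the call under the empirical null.

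Clock genes moved in both directions. Of 40 tested members of the circadian list, 7 were higher and 13 lower in the authors' deposited table, and 27 passed when adjusted over the list alone. The light-inducible genes per2 (-0.62, SE 0.0612; DESeq2 adjusted p = 1.79e-20) and cry5 (-0.70, SE 0.0664; adjusted p = 2.50e-22) were 1.53-fold and 1.63-fold lower in the authors' deposited table. Also lower in the authors' deposited table were the repressor genes bhlhe41 (-0.60, SE 0.0714), per1a (-0.41, SE 0.104) and nr1d1 (-0.36, SE 0.0788). Higher beside rorcb in the authors' deposited table were arntl1b (0.48, SE 0.0744), which encodes the activating partner of CLOCK, and rorca (0.45, SE 0.0853), both chosen after their values were seen. With members going both ways, the list as a whole had a median of -0.07 and a cameraPR adjusted p of 0.00139, which rose to 0.0561 at a preset correlation of 0.05 and to 0.289 on ranks. After the shift to equal sums 9 members were higher and 11 lower and the median was -0.03, and under the empirical null 4 were higher and 7 lower, with per1a and nr1d1 losing the call.

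**Figure D2:**
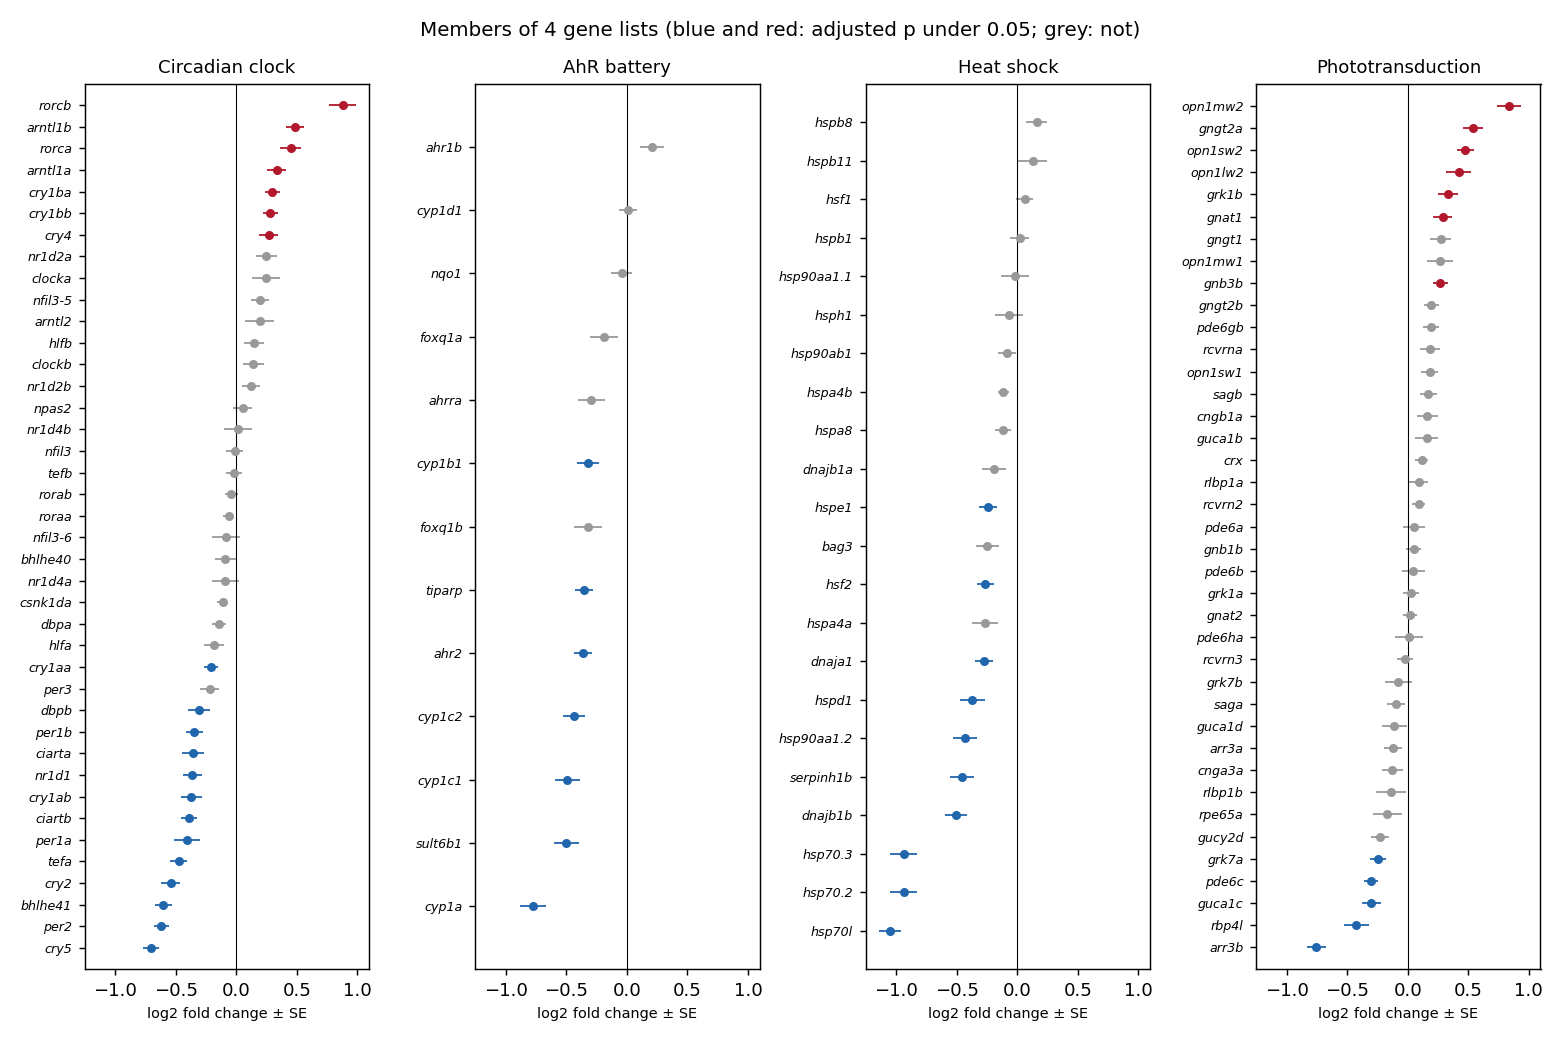
Deposited log2 fold change with its SE (horizontal axis, negative read as lower with TCPMOH) for the tested members of 4 gene lists, 1 gene per line, with 1 member not shown. Blue and red points passed an adjusted p under 0.05 in the authors' DESeq2 Wald test as lower and higher, and grey points did not. The clock list holds 13 lower and 7 higher members, the aryl hydrocarbon receptor list 7 lower, the heat shock list 10 lower and the phototransduction list 5 lower and 7 higher.

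Genes of the aryl hydrocarbon receptor (AhR) battery were lower with TCPMOH. In the authors' deposited table cyp1a, the receptor's classical target, stood at -0.78 (SE 0.107; DESeq2 adjusted p = 3.04e-10), 1.71-fold lower, at a base mean of 21956. It lies on chromosome 18 from 5588068 to 5598958. The related cyp1c1 (-0.49, SE 0.0998), cyp1c2 (-0.44, SE 0.0901) and cyp1b1 (-0.32, SE 0.0904; DESeq2 adjusted p = 0.0216) and the sulfotransferase gene sult6b1 (-0.50, SE 0.103) were lower in the authors' deposited table. So were the receptor gene ahr2 (-0.36) and tiparp (-0.35), a repressor of the receptor, both chosen after their values were seen in the authors' deposited table. In all, 7 of 13 tested members were lower and 0 higher, 9 passed when adjusted over the list alone, and the list's median was -0.32 (cameraPR adjusted p = 4.76e-12). The receptor repressor gene ahrra did not pass, at -0.29 (SE 0.112; DESeq2 adjusted p = 0.160) in the authors' deposited table. The call of cyp1b1 was lost after the shift to equal sums (adjusted p = 0.0696), after removal of the span trend (adjusted p = 0.0584) and under the empirical null (adjusted p = 0.344), all recomputed from the DESeq2 statistics, and 5 members of the list stayed lower under the empirical null.

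The lists of pregnane X receptor and phase I genes (34 tested, 2 lower, median -0.13, cameraPR adjusted p = 4.84e-06), of conjugating enzymes (40 tested, 3 lower, median -0.11, adjusted p = 7.87e-07) and of glutathione and NRF2 genes (32 tested, 3 lower, median -0.13, adjusted p = 9.12e-06) were also shifted down, by smaller medians, with 0 members higher in each. Their medians were nearer to 0 than that of the intestinal markers described below (-0.17, 19 of 20 negative), and a smaller share of intestine cells was not tested for these lists. Adjusted over the list alone, 4, 11 and 7 members passed. The glucuronosyltransferase genes ugt1b1 (-0.54, SE 0.0876) and ugt1b5 (-0.50, SE 0.0980) were lower in the authors' deposited table, but their coordinates overlap on chromosome 11 and reads could be shared between them. Lower too in the authors' deposited table were abcg2a (-0.44), cyp2y3 (-0.30), gsta.1 (-0.33), the NRF2 paralog gene nfe2l2b (-0.39), gclc (-0.23), which encodes the catalytic subunit that starts glutathione synthesis, and pgd (-0.19). Not passing in the authors' deposited table were cyp3a65 (-0.15; DESeq2 adjusted p = 0.615), gstp1 (-0.07; adjusted p = 0.709) and hmox1a (-0.34; adjusted p = 0.0759). After the shift to equal sums 1, 2 and 1 members of the 3 lists were lower, with medians of -0.08, -0.07 and -0.08. Under the empirical null 0, 2 and 0 were lower, the 2 being ugt1b1 and ugt1b5.

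Heat shock genes were lower with TCPMOH. In the authors' deposited table hsp70l, an inducible chaperone gene, stood at -1.05 (SE 0.0930; DESeq2 adjusted p = 1.23e-25), 2.07-fold lower, on chromosome 8 from 4798158 to 4800911. The tandem copies hsp70.2 and hsp70.3 stood at -0.94 each in the authors' deposited table (SE 0.113 each). These 3 genes are similar in sequence, and how reads were divided among them is uncertain. The co-chaperone gene dnajb1b was lower at -0.51 (SE 0.0940) in the authors' deposited table. Of 22 tested members 10 were lower and 0 higher, 13 passed when adjusted over the list alone, and the median was -0.24 (cameraPR adjusted p = 5.50e-17). The count of lower members was 6 after the shift to equal sums and 4 under the empirical null.

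Photoreceptor genes also split. The cone opsin gene opn1mw2 (green cones) was higher at 0.84 (SE 0.101; DESeq2 adjusted p = 1.94e-13), 1.78-fold, and opn1sw2 (blue cones) at 0.48 (SE 0.0688; adjusted p = 3.58e-09) in the authors' deposited table. The cone transducin subunit gene gngt2a (0.54, SE 0.0825) and the opsin gene opn6b (0.68, SE 0.101) were higher, and the cone arrestin gene arr3b was lower at -0.75 (SE 0.0808; DESeq2 adjusted p = 2.36e-17), per the authors' deposited table. Because opn1mw2 belongs to a tandem array of similar green opsin genes, its share of their reads is uncertain. A difference in light or time of day at collection was not tested for the photoreceptor genes. Of 40 tested members of the phototransduction list 7 were higher and 5 lower, 20 passed when adjusted over the list alone, and the median was 0.07 (cameraPR adjusted p = 0.00502). That adjusted p rose to 0.0935 at a preset correlation of 0.05 and to 0.0551 on ranks, and 11 members were higher and 4 lower after the shift to equal sums (median 0.12), against 3 and 2 under the empirical null.

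Several large groups shifted by little per gene. Cytosolic ribosomal protein genes had a median of -0.14 (95% bootstrap interval -0.15 to -0.13), with 80 of 81 negative and a cameraPR adjusted p of 1.85e-10, yet 0 were called by the authors' DESeq2 test and 5 had an unadjusted p under 0.05. After the shift to equal sums their median was -0.09, with 80 negative. Nuclear genes of the respiratory chain had a median of -0.10, with 66 of 69 negative (cameraPR adjusted p = 4.11e-07), and of -0.05, with 56 negative, after the shift. Of these, sdha (-0.22, SE 0.0464) and uqcrh (-0.19, SE 0.0564) were lower in the authors' deposited table, and 2 passed when adjusted over the list alone, but uqcrh lost the call after the shift, under the empirical null and with the span trend removed. Both lists are of short genes (median span 5971 and 5833 bp), and short genes tended to be lower overall. With the span trend removed the ribosomal protein median was -0.10 (cameraPR adjusted p = 7.84e-07) and the respiratory chain median -0.07 (adjusted p = 2.64e-04). At a preset correlation of 0.05 the cameraPR adjusted p was 6.54e-04 for ribosomal protein genes and 0.00346 for the respiratory chain. The correlation among the members is unknown here, and a higher one would raise these values further. Proliferation genes shifted up, with a median of 0.13 and 39 of 43 positive (cameraPR adjusted p = 5.39e-06), while the authors' DESeq2 test called 0 and 7 had an unadjusted p under 0.05. Their median was 0.14 with the span trend removed, and their cameraPR adjusted p was 0.00399 at a preset correlation of 0.05. The interferon list had 8 tested members, all positive, with a median of 0.11 and a cameraPR adjusted p of 0.0211, which was 0.0585 at a preset correlation of 0.05 and 0.137 without the filter on low means. None of its members was called by the authors' DESeq2 test, and 2 had an unadjusted p under 0.05.

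Intestinal epithelium markers were lower as a list (20 tested, median -0.17, cameraPR adjusted p = 2.79e-05), with apoa4a, an apolipoprotein gene (-0.41, SE 0.113), and the meprin gene mep1a.2 (-0.34, SE 0.106) called in the authors' deposited table. Adjusted over the list alone 4 passed. After removal of the span trend the list still passed (median -0.15, cameraPR adjusted p = 3.02e-04), while apoa4a at -0.36 (adjusted p = 0.0585 from the DESeq2 statistics) and mep1a.2 at -0.30 (adjusted p = 0.120), with SEs as before, did not. Neither was called under the empirical null. In the p53 list 4 of 25 tested members were lower and 0 higher (cameraPR adjusted p = 0.0198), and 4 passed when adjusted over the list alone. They were xpc, ddb2 (-0.45, SE 0.0985), cdkn1a (-0.46, SE 0.112) and gadd45ab (-0.35, SE 0.0990) in the authors' deposited table, of which xpc and ddb2 recognize DNA damage for nucleotide excision repair. The gene xpc is also in the light-induced arm of genes described below. Under the empirical null xpc alone stayed lower, with adjusted p = 0.0688 for ddb2 and 0.145 for cdkn1a from the DESeq2 statistics. The median of the p53 list was near 0 at -0.01 and turns positive with the shift to equal sums, and the list's cameraPR adjusted p was 0.101 after removal of the span trend, 0.120 at a preset correlation of 0.05 and 0.289 on ranks.

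**Figure D3:**
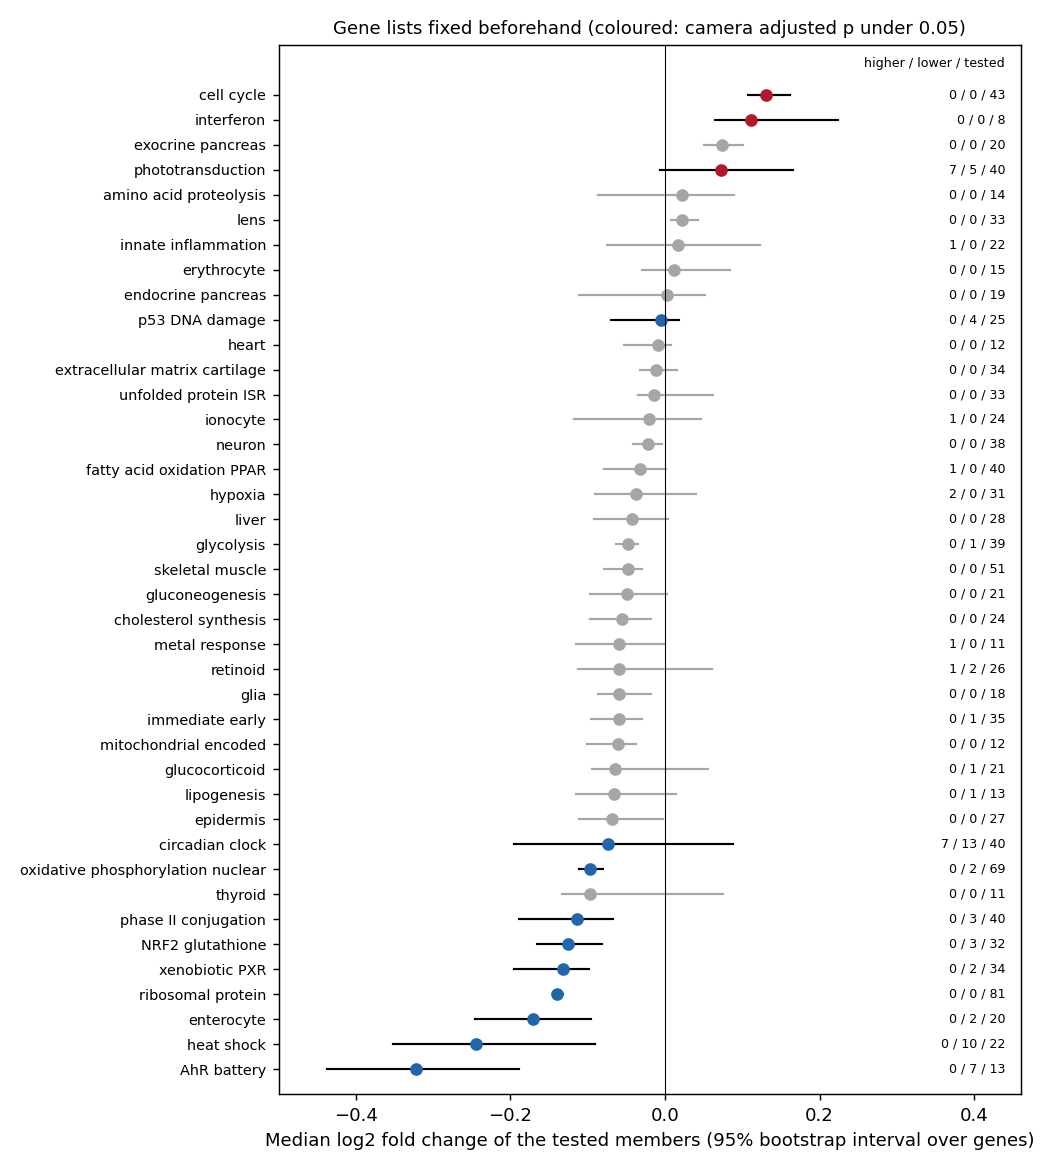
Median log2 fold change (horizontal axis, negative read as lower with TCPMOH) of the tested members of the 40 lists run, with 95% bootstrap intervals over genes. Blue and red points passed the cameraPR test as lower and higher at an adjusted p under 0.05, and grey points did not. Numbers at the right give the members called higher, called lower and tested. The medians run from -0.32 for the AhR battery to 0.13 for the cell cycle list.

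The other 27 lists run did not pass (cameraPR adjusted p from 0.0557 to 0.989), and their medians lay between -0.10 and 0.07. The exocrine pancreas list, with 20 of 20 members positive, passed cameraPR without the filter on low means (adjusted p = 0.0449), on ranks (0.0126) and with the span trend removed (0.00216). Without the filter the lists of glycolysis (0.0183), immediate early genes (0.0148), cholesterol synthesis (0.0288), skeletal muscle (0.0485) and mitochondrial transcripts (0.0332) also passed, all as lower, and so they did on ranks (0.0245, 0.0244, 0.0499, 0.0286 and 0.0286). Immediate early genes passed after the shift to equal sums as well (0.0364), and the lens list passed as higher with the span trend removed (0.0271), by adjusted p from cameraPR. Of their 646 different tested genes, 6 were higher and 6 lower in the authors' deposited table (DESeq2 Wald test). The retinoid list held the retinoic acid hydroxylase genes cyp26c1 (-0.44, SE 0.0886) and cyp26a1 (-0.35, SE 0.0959) as lower and the receptor gene rxraa (0.21, SE 0.0592) as higher, per the authors' deposited table. Single members elsewhere in the authors' deposited table were pdk4 (0.27), ndrg1a (0.28), the iron hormone gene hamp (0.34) and the calcium channel gene trpv6 (0.42) as higher, and gadd45bb (-0.41), acaca (-0.25) and pgam1a (-0.19) as lower. The estrogen list had too few tested members for the list test, and its srd5a2a was lower at -0.27 (SE 0.0782) in the authors' deposited table. Of these single members cyp26c1 alone kept the call under the empirical null. Lists for liver, lens, skeletal muscle, heart, erythrocytes, neurons, glia, epidermis, exocrine and endocrine pancreas, cartilage matrix, gluconeogenesis, cholesterol synthesis, the thyroid axis, the unfolded protein response, muscle proteolysis and mitochondrial transcripts held 0 calls among 407 genes by the authors' DESeq2 test, with 24 at an unadjusted p under 0.05. The signs of median and test differed for the unfolded protein list (-0.01, tested up), the endocrine pancreas list (0.0030, tested down) and the cartilage matrix list (-0.01, tested up), none of which passed. Of the genes always reported, pck1 (-0.09; DESeq2 adjusted p = 0.801), ins (-0.28; adjusted p = 0.125) and fkbp5 (0.05; adjusted p = 0.890) did not pass, and vtg1 had no adjusted p at a base mean of 6.08, per the authors' deposited table.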

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

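No paired analysis was possible because the table holds no values per library, so the planned replicate block, leaving out replicates, other normalizations and count tools, pseudocounts, the fit of all 15 libraries, fry, an estimated correlation and every TCPM comparison were not run, nor were other splits of the samples. Planned thresholds moved the 516 calls (146 higher, 370 lower) to 275 (68 and 207) at an adjusted p under 0.01, raised the higher genes to 231 at 0.1, and left 3 (0 and 3) at an absolute log2 fold change of at least 1, as stricter or looser cuts must. Without a low-mean filter 433 were called, and 517 at a base mean of at least 50. The remaining alternatives were chosen after seeing the data. The shift to equal sums called 355 higher and 218 lower, 364 of all 573 shared with the 516. The 10 most abundant genes held 9.77% of the summed base means, and without them the shift was -0.04, against -0.05 with them. The empirical null called 121 (28 and 93), removal of the span trend 481, and both together 176 (42 and 134). The cause was not tested. Of 67 named genes, none reversed in any of these alternatives, 26 lost the call under the empirical null, 24 with both, 17 at 0.01, 12 after the shift, 10 without the span trend and 6 without the filter, and hmox1a passed at 0.1. With the inferred shrinkage undone 15 called genes reached 1 (4 and 11), with cyp1a at -1.03 and fgf23 at -1.35. Of the 40 lists, 13 passed, against 9 to 18 under the alternatives. Depth per library is unknown, so its effect was not tested.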

Other observations

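Chosen after the results were seen were the ribosome biogenesis list, the clock arms, the test on light or time of day, the symbol families, the gene span alternatives, the neighbour count, and the tests on tissue share and on the AhR list without the span trend. Ribosome assembly factors were lower as a group. Of 108 tested genes, 38 were lower and 0 higher in the authors' deposited table, 106 had a negative fold change, and the median was -0.24. Among them were the export adaptor gene nmd3 (-0.38, SE 0.0705; DESeq2 adjusted p = 1.65e-05), tbl3 (-0.36, SE 0.0773), tsr1 (-0.33, SE 0.0692) and the nucleophosmin gene npm1a (-0.37, SE 0.0962) in the authors' deposited table. The list was assembled from these data, so its count is not independent evidence, and 19 members were lower after the shift to equal sums and 4 under the empirical null.

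Genes were also grouped by the leading letters of their symbols. Of 220 such families with at least 10 tested genes, 37 passed cameraPR, 15 up and 22 down, and 24 passed in the same direction without the span trend. Opsin (opn) genes shifted up, with a median of 0.25 over 14 genes, 4 higher and 1 lower (cameraPR adjusted p = 3.66e-08). The one lower was opn6a at -0.40 (SE 0.0866) in the authors' deposited table, while its paralog opn6b was higher. The replication licensing (mcm) family stood at a median of 0.21 over 10 genes (adjusted p = 9.73e-05 by cameraPR) and the protocadherin (pcdh) family at 0.14 over 29 (adjusted p = 5.89e-06), and mitochondrial ribosomal protein (mrpl) genes stood at -0.15 over 46 (adjusted p = 1.07e-08). In each of these families the authors' DESeq2 test called 0 genes. The pcdh genes are long (median span 65457 bp) and the mrpl genes short (6560 bp). Without the span trend their cameraPR adjusted p was 2.16e-04 and 3.33e-06. Of the 516 called genes, 215 had another called gene of a different family within 500 kb, against a median of 188 and a range of 142 to 227 in 1000 random draws matched on base mean, of which 2.2% were as large. The draws were not matched on gene span or on local gene density, which could also raise the count.

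Clock genes changed in 2 directions, with 7 members of the circadian list higher and 13 lower. Among genes grouped after their values were seen, a light-induced and daytime arm of 21 genes (per, cry5, tefa, nr1d1, xpc and related genes) had 16 lower and a median of -0.37, and an arntl, clock and ROR arm of 11 had 6 higher and a median of 0.28. The arms were picked on these data and leave out nr1d2a and nr1d2b (0.25 and 0.12 in the authors' deposited table) and roraa and rorab (-0.06 and -0.04), so they are not independent evidence of a split. Removal of the span trend left their difference at -0.65 and left 7 list members higher and 12 lower. The medians of all tested genes ran only from -0.04 to 0.05 over 5 bins of span. A trend of that size is too small for the arms' difference, so its removal could not have closed it and adds no separate support. A difference in light or time of day at collection between the groups may also move 7 clock genes up and 13 down. It cannot be told apart from an effect of TCPMOH, which was untested, since the labels give no collection times. Such a difference need not be limited to clock genes, and it was not tested for the photoreceptor genes or separately for xpc.

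The cyp1 genes were lower together with other AhR targets. The AhR list's median (-0.32) lay below those of the liver (-0.04) and skin (-0.07) markers, with bootstrap intervals of the difference up to -0.13 and -0.12. These markers fell by less, which argues against a smaller share of liver or skin cells as the whole cause. The comparison was chosen when the AhR list was known to have the lowest median, and its intervals resample genes, not pools. It is therefore not an independent test, and other tissues apart from intestine were not compared. For intestine the interval reached 0.0043, and that list was itself lower (median -0.17), so a smaller share of intestine cells may contribute and cannot be told apart from an effect of TCPMOH, which was untested. The medians of all tested genes ran only from -0.04 to 0.05 over 5 bins of span, against -0.32 for the AhR list. A trend of that size is too small to be the whole cause of the list's fall. Its removal could therefore not have closed the difference, and the list test without it (cameraPR adjusted p = 1.26e-11) adds no separate support. Of the 7 called genes 6 kept the call and the median moved from -0.44 to -0.41. The call of cyp1b1 was lost as its fold went from -0.32 to -0.29 with an unchanged SE of 0.0904, so for cyp1b1 a contribution of the span trend stays open.

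Short genes tended to be lower and long genes higher. Across the 19257 tested genes, which are not independent replicates, Spearman's correlation between genomic span and log2 fold change was 0.257, and medians rose from -0.04 in the shortest of 5 equal bins (median span 4.51 kb) to 0.05 in the longest (95.3 kb). The shift to equal sums would turn the negative medians positive and keep the order. Without called genes, listed genes and ribosome assembly genes the correlation was 0.253 over 17640 genes, which argues against those groups as the source. Families of short genes outside the lists were not removed. The correlation ranged from 0.180 to 0.375 over 5 bins of base mean, so a length-dependent difference in RNA or library quality may contribute, and it cannot be told apart from an effect of TCPMOH because transcript lengths and quality values per library were not analysed here.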
